A study of Danio rerio with 7 samples.

How the data were processed

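The comparison rests on 6 bulk RNA-seq libraries from pooled heads of zebrafish (Danio rerio) larvae at 5 days post fertilization (dpf), 3 from wild type (WT) larvae and 3 from larvae that the labels call hm41 mutant, without saying whether they were homozygous. Per the labels' protocols, RNA was extracted with a column kit, and directional libraries were prepared from total RNA. The libraries are named here by the numbers in their labels: WT 66, 67 and 68, and hm41 69, 70 and 71. All 6 numbers differ, so the labels pair no samples and name no batch. The series holds 7 samples. The remaining 1 is a single-cell library that mixes genotypes and ages in its label, which puts it in no group, and it was not analysed here.

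The authors deposited expected counts, that is, read counts estimated per gene and not scaled between libraries, for 30421 gene rows. RSEM, TopHat, Bowtie2 and the genome build GRCz11 are named per the submitters' processing notes, with no role, order or version. The annotation release, the trimming and the strand setting are not given in the sources used here. Between 17.8% and 23.2% of the values per library, rows at 0 included, were not exactly whole (no tolerance), and all values were rounded to whole counts before testing. No row without a gene name was present, and 2679 rows were 0 in all 6 libraries.

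Total counts per library were 114604258, 35073495 and 74806172 in WT 66, 67 and 68, and 33775984, 70534872 and 42732238 in hm41 69, 70 and 71. The 8 most abundant rows held between 93.6% and 95.7% of the counts in each library. One of these, zgc:158463, is annotated as ribosomal RNA in the RefSeq gene table of GRCz12tu. Without these rows, 4959749, 1664845 and 4775725 counts were left in the WT libraries and 2142623, 4509187 and 2341271 in the hm41 libraries, so the depth for other genes was low. Levels in CPM (counts per 1e6 counts) are relative to the totals scaled by the normalization factors, and are small for this reason. The median tested gene had a mean of 63 counts per library. The row LOC110438492 held 5141165, 2743068 and 2589780 counts in WT 68, hm41 70 and hm41 71 and at most 6 in each of the others, a split that does not follow genotype.

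Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust estimation, trimmed mean of M-values (TMM) normalization and no covariate. Genes were kept by edgeR's filterByExpr function (19275 genes), p-values were two-sided, and the false discovery rate was held at 0.05 by the Benjamini-Hochberg method. Genes past this threshold are called here. Fold changes are log2 values of hm41 over WT, given with their standard error (SE) or 95% confidence interval. Levels are means ± SD of the 3 libraries in CPM. For a called gene with no count in hm41, the fold was bounded with a floor of 3 counts summed over the hm41 group. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules.

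Before the data were examined, 40 lists of genes were fixed, of cell types of the larval head and of pathways, with 1287 symbols, of which 1257 matched a row of the table directly or through synonyms. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01. The Benjamini-Hochberg method was applied over the 40 lists. Camera with the correlation estimated per list and fry were run as alternatives. Members were also counted after adjustment over the list alone. Another 3 lists, of xanthophore, iridophore and melanophore genes, were written after the called genes were seen.

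File identifiers were matched to the RefSeq gene table of GRCz12tu, which is not the authors' build. That table was used only for names, chromosomes and neighbours, and 25045 of the 30421 identifiers matched a gene. Enrichment of called genes on each of 25 chromosomes, and within 5 Mb of spock1, was tested with Fisher's exact test, two-sided, over 17556 tested genes placed on a chromosome, with scipy 1.17.1. Circular shifts of the calls along the gene order were drawn 10000 times.

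The genes named in the text follow a rule fixed before the data were examined: spock1, spock2 and spock3; mcamb, a gene known from the study's published work; up to 10 genes with the largest increase and 10 with the largest decrease among called genes with an assigned symbol, a mean of at least 1 CPM and no overlap between the groups, the 6 genes with the smallest p, up to 8 called genes nearest to spock1 on chromosome 14, and up to 4 members with the smallest p of each called list or list with called genes. Few genes passed, so fewer are named. Names outside the rule are marked as chosen after their values were seen.

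The steps were tested on simulated data. Counts for the real genes were drawn from their means, dispersions and the real library sizes, with 200 genes changed by known folds. Of 50 genes for each fold, the edgeR test over 19031 genes recovered 4 at 1.5-fold, 28 at 2-fold, 40 at 4-fold and 44 at 10-fold. It made 126 calls, 8 of them on genes that had not been changed. Camera called the planted list and 0 of 40 unchanged lists. The simulated genes were drawn independently of each other, while the estimated correlation between members of the real lens list was 0.798. How often camera calls unchanged lists whose members vary together was therefore not tested by simulation. With calls placed at random 200 times, Fisher's exact test passed 0.05 in 12 and the circular shifts in 6.

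Alternatives were other normalizations (relative log expression, upper quartile, library totals alone), DESeq2 1.42.0, limma voom, no filter on low counts, a filter of at least 2 CPM in at least 3 libraries, a test against a 1.2-fold change, false discovery rates of 0.01 and 0.1, estimation without robustness, removal of the 50 most abundant genes, and each library left out in turn. Added after seeing the data were the removal of the 8 most abundant rows, a term for the LOC110438492 split, lists without shared members, and the xanthophore list without aox5. Gaps between gene sets were compared as mean log2 CPM per library, with 0.5 added to each count, by their spread between libraries and by exact permutation of the 6 libraries. Nothing in the labels says that the pools came from separate clutches, so p-values measure only the spread between these samples, which may be technical in part. As a check for a library deposited more than once, counts of replicate libraries were compared, and no pair agreed within sampling noise (chi-square per degree of freedom 13.6 to 519.7), which does not show that the pools are independent.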

Results

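The hm41 mutation belongs to a zebrafish line that the submitters call leaky, in a series whose title concerns the blood-brain barrier, the seal that brain vessels form against the blood. Bulk RNA-seq of pooled heads from mutants and their WT siblings at 5 dpf served to find the lesion, and the design text reports linkage to chromosome 14 and to spock1. Spock1 is a secreted proteoglycan of the extracellular matrix. The 6 libraries, 3 per genotype, held between 33775984 and 114604258 counts, of which 1664845 to 4959749 fell outside the 8 most abundant rows. WT 67 had the fewest of these and stood apart from the other libraries on the principal component that held 33.1% of the variance (score -70.4, against -14.1 to 39.3 for the others). On the component with 23.9% of the variance hm41 69 stood apart (score 59.4, against -39.0 to 8.1 for the others). For WT 67 the mean correlation with the other libraries over log CPM was 0.906, against 0.921 to 0.935.

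The abundance of spock1 itself did not differ detectably between the genotypes. It had 2.25 ± 0.464 CPM in WT and 1.74 ± 0.420 CPM in hm41 (SD, n = 3 each). The log2 fold change was -0.38 (95% confidence interval -0.87 to 0.10; adjusted p = 0.594 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the same fit its relatives had higher values in every hm41 library than in any WT library without passing the threshold: spock2 had a log2 fold change of 0.47 ± 0.168 (SE, adjusted p = 0.308) and spock3 one of 0.56 ± 0.165 (SE, adjusted p = 0.205). Such a lack of overlap, in either direction, was seen for 16.5% of all tested genes and is not particular to them. For mcamb, which encodes a cell adhesion molecule of the vessel wall, the log2 fold change was 0.22 (95% confidence interval -0.26 to 0.70; adjusted p = 0.8).

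Among all 19275 genes tested, 11 differed between hm41 and WT heads, 3 higher and 8 lower in hm41. At an unadjusted p under 0.05 there were 2006 genes, where 964 would be expected by chance, and 3187 genes (16.5%, against 10% by chance) had no overlap between the WT and the hm41 libraries. Splits of the libraries that mix the genotypes gave 436 to 1413 genes at that p, most in the split that follows LOC110438492. The lower genes included csf1ra, the receptor kinase for colony stimulating factor 1 that macrophages, microglia and yellow pigment cells (xanthophores) need. It fell 10.3-fold, from 1.38 ± 0.398 CPM to 0.137 ± 0.023 CPM (SD; log2 fold change -3.36 ± 0.378, SE; adjusted p = 0.000171, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A pi-class glutathione S-transferase gene, gstp2, fell 12.5-fold (-3.65 ± 0.407, adjusted p = 0.00131), while its close paralog gstp1, named after its values were seen, had a log2 fold change of -0.11 ± 0.153 (SE). The sign of that value turned with library totals alone (0.12), which moves the median of all genes by 0.22. Aldehyde oxidase 5 (aox5), a xanthophore gene named after its values were seen, fell 13.1-fold (-3.71 ± 0.592, adjusted p = 0.0107). The clustered protocadherin pcdh2g17, a neuronal adhesion gene, fell by 1.74 on the log2 scale (adjusted p = 0.0414), and LOC107195253 fell by the same amount (adjusted p = 0.00592). Both gstp2 and pcdh2g17 have near-identical neighbours, and how their reads were divided is uncertain.

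The other 3 lower genes had no count in any hm41 library. LOC100535907 had 179 counts over the 3 WT libraries and was at least 46.5-fold lower in hm41, LOC108192086 had 155 and was at least 40.3-fold lower, and LOC101882031 had 112 and was at least 29.1-fold lower, each against a floor of 3 counts over the hm41 group. The genes that rose were atp1b2b, a beta subunit of the sodium-potassium pump (2.22-fold; log2 fold change 1.15 ± 0.174, adjusted p = 0.00592), napba, an attachment protein used in taking apart synaptic vesicle fusion complexes (1.88-fold; 0.91 ± 0.152, adjusted p = 0.0182), and opn1sw1, the ultraviolet cone opsin (2.09-fold; 1.06 ± 0.188, adjusted p = 0.0328), all by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

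**Figure D1:**
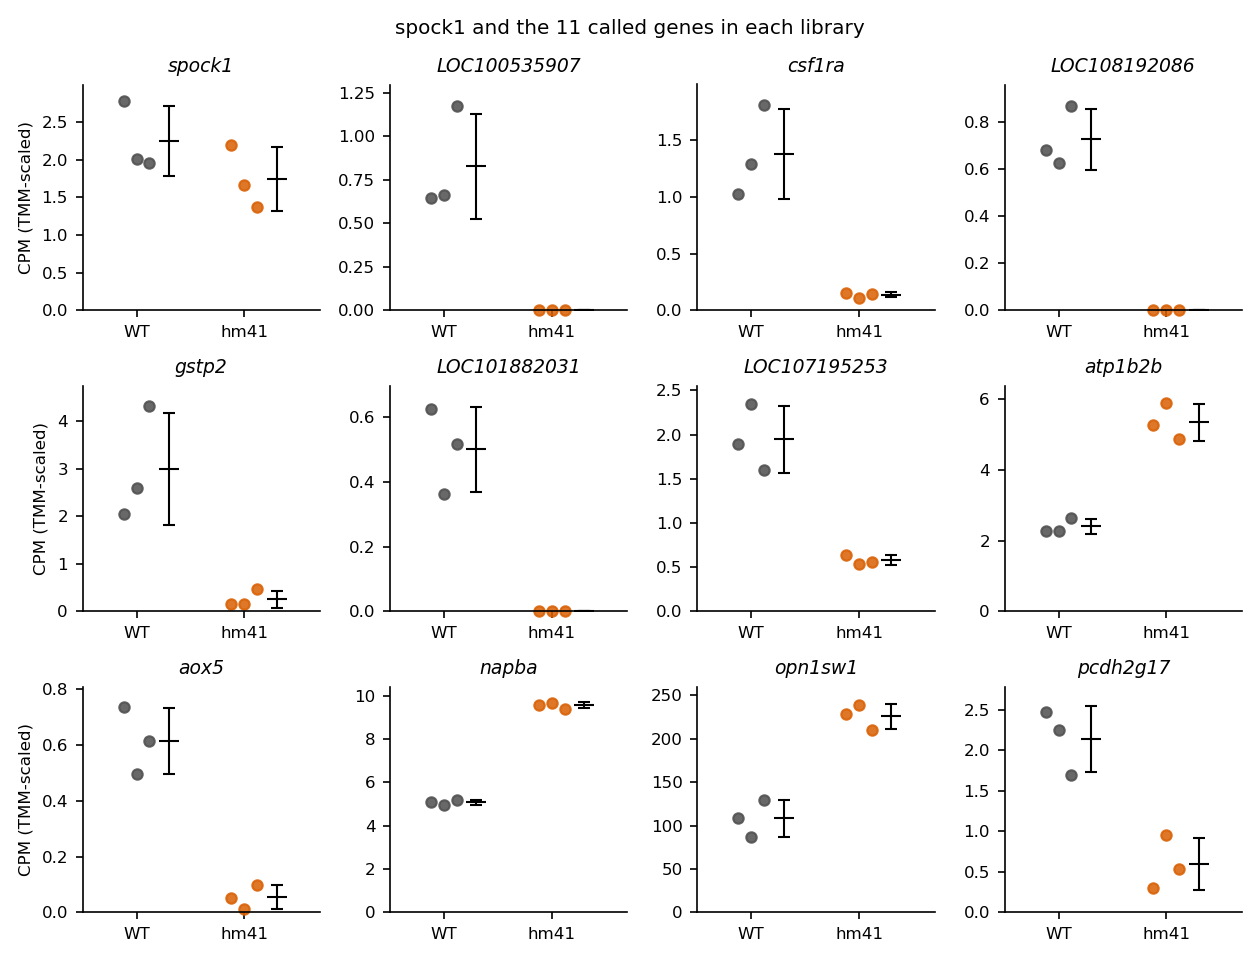
Each panel plots the level of 1 gene in CPM on an axis that starts at 0, with 1 point for each of the 3 WT (grey) and 3 hm41 (orange) libraries and, beside them, the mean and SD. The hm41 points of csf1ra lie near 0.137 CPM against 1.38 CPM in WT and those of LOC100535907, LOC108192086 and LOC101882031 at 0, while the groups overlap for spock1.

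The count of called genes depended on the libraries and the tool: it was 44 without WT 68, 20 without hm41 69 and 6 without hm41 70, and DESeq2 called 199 genes (139 higher, 60 lower), of which 2 were among the 11. The other 9 got no adjusted p from DESeq2, while its unadjusted p for all 11 lay between 1.12e-17 and 1.58e-06, with log2 fold changes such as -3.36 for csf1ra and 1.17 for atp1b2b. Scaling by library totals alone moved the median log2 fold change of all genes by 0.22 and gave 32 higher and 15 lower genes against 3 and 8. Of the 11 genes, csf1ra, gstp2, LOC100535907, LOC108192086 and LOC101882031 were called in each of the 6 fits without 1 library. Without 1 library the log2 fold change of gstp2 reached -4.29 (hm41 71), that of pcdh2g17 -2.33 (hm41 70) and that of aox5 -3.03 (hm41 70) and -4.48 (hm41 71). The other 6 were not called in every fit. LOC107195253 was lost without hm41 70 (adjusted p = 0.127), aox5 and atp1b2b were lost without WT 66 or hm41 70 (highest adjusted p 0.142 and 0.132), and napba, opn1sw1 and pcdh2g17 were each lost in 4 of the 6 fits (highest adjusted p 0.147, 0.277 and 0.21). For napba and opn1sw1 these were the fits without WT 66, WT 67, hm41 70 or hm41 71, and for pcdh2g17 those without WT 66, WT 67, hm41 69 or hm41 71.

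Called genes gathered on chromosome 14, the chromosome named in the design text. Of the 9 called genes with a place in GRCz12tu, 5 lay there among 622 tested genes, against 4 among 16934 tested genes elsewhere (odds ratio 34.3, Fisher's exact test p = 6.15e-06, adjusted p = 0.000154 over 25 chromosomes). Within 5 Mb of spock1 there were 4 called genes among 137 tested, against 5 among 17418 (odds ratio 104.7, Fisher's exact test p = 4.34e-07). These 4 were csf1ra, LOC108192086, gstp2 and pcdh2g17, all lower in hm41. In gene order, 6 genes of the table separated csf1ra from spock1, 11 separated LOC108192086 and 15 gstp2, while LOC107195253 lay 315 genes away. For pcdh2g17, within 2 Mb of spock1, no such count is given. The protocadherin genes around it share a start in that annotation and so have no order among themselves. The remaining placed genes were aox5 on chromosome 22, atp1b2b on 5, napba on 17 and opn1sw1 on 4. LOC100535907 and LOC101882031 had no match in that annotation. The order is that of GRCz12tu, not of GRCz11, the build named in the submitters' processing notes. With genes at an unadjusted p under 0.01 in place of called genes, the odds ratio was 1.6 for chromosome 14 (31 of 622 genes) and 3.4 for the region around spock1. The odds ratio of chromosome 14 was 55.3 without WT 66, 5.5 without WT 68 and 10.7 without hm41 69, and that of the region 21.3 without WT 68 and 25.7 without hm41 69. Without hm41 70 all 4 placed calls lay in the region, which leaves no finite ratio. With a term for the LOC110438492 split, pcdh2g17 was no longer called (adjusted p = 0.0727, log2 fold change -1.80), which left 3 called genes in the region.

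**Figure D2:**
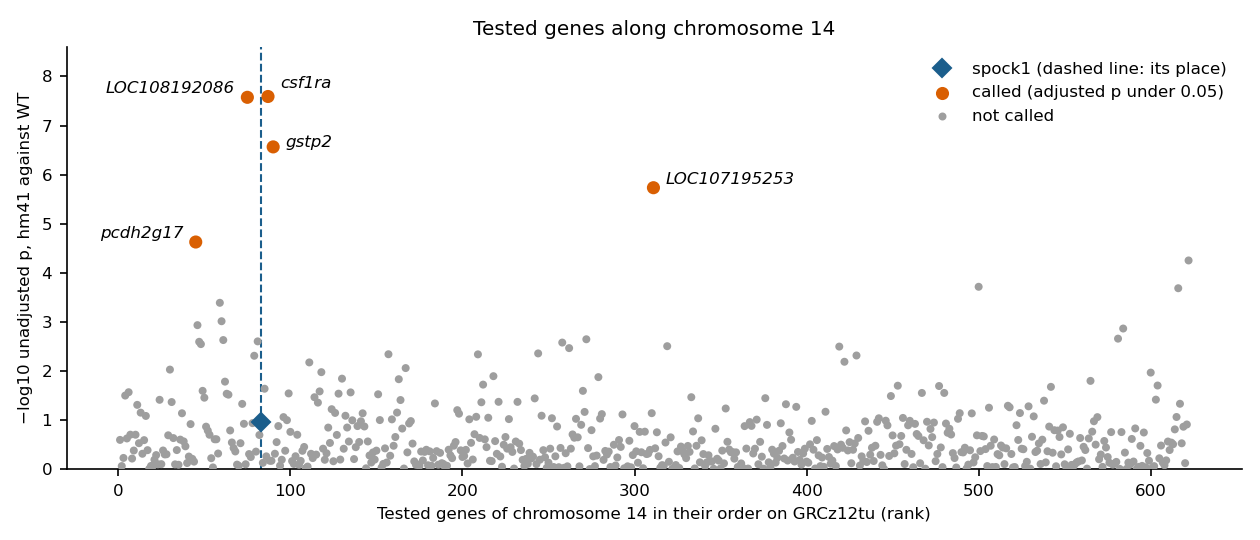
The 622 tested genes of chromosome 14 are shown in their order on GRCz12tu (horizontal axis, rank). Genes with the same start, as in the protocadherin clusters, are ranked by p and not by place. The vertical axis gives the −log10 of the unadjusted p for hm41 against WT. Called genes are orange, other genes grey, and spock1 is a blue diamond on a dashed line. Of the 5 called genes, 4 stand close to spock1, which itself is not called.

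Of the 40 lists, camera called 15, 11 higher and 4 lower in hm41, and with an estimated correlation it called 0 (1 list at an unadjusted p under 0.05). Called higher were lists of the eye, neurons and glia. Of 45 tested photoreceptor genes, 11 rose adjusted over the list alone and 1 (opn1sw1) over all genes, with a list median of 0.35 on the log2 scale. Lower values were seen for 7 members, none of which passed either adjustment. Those that rose included the cone channel subunit cnga3a (0.91 ± 0.210, SE), the green cone opsin opn1mw1 (0.74 ± 0.175) and the outer segment protein prph2a (0.73 ± 0.173). Of 32 neuron genes, 5 rose adjusted over the list alone and 0 over all genes (list median 0.32), among them stmn2b (0.74 ± 0.169), elavl4 (0.67 ± 0.157), the synaptic vesicle protein gene sv2a (0.77 ± 0.187) and gad1b, which encodes an enzyme of GABA synthesis (0.56 ± 0.162). Radial glia genes behaved alike, with 5 of 26 that rose adjusted over the list alone, 0 over all genes and a median of 0.26. Examples were the gap junction gene cx43 (0.57 ± 0.156), the water channel aqp4 (0.87 ± 0.246) and the glutamate transporters slc1a2a (0.61 ± 0.192) and slc1a2b (0.64 ± 0.204). The lens list had the highest median (0.69), with 25 of 26 members above 0 but 1, cryaa (1.83 ± 0.396), that rose adjusted over the list alone and 0 over all genes. For gja3, crygm5 and lim2.1 the log2 fold changes were 1.31, 1.18 and 1.01. Without WT 68 the values were 2.59 for cryaa, 2.28 for crygm5 and 2.18 for lim2.1. Camera called these 4 lists at adjusted p-values of 1.12e-09 (photoreceptors), 3.93e-06 (neurons), 7.43e-05 (radial glia) and 6.71e-07 (lens). None of these calls held when the correlation between members was estimated: the adjusted p was 0.568 for photoreceptors, neurons and radial glia and 0.75 for the lens with an estimated correlation.

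Camera called the lists of ribosomal protein, mitochondrially encoded and epidermal genes lower in hm41. Of 67 ribosomal protein genes, 62 had negative values, 20 fell adjusted over the list alone and 0 over all genes (median -0.28). They included rpl26 (-0.85 ± 0.188, SE), rpl23 (-0.78 ± 0.177), rps24 (-0.65 ± 0.163) and rpl15 (-0.67 ± 0.172). Of the 13 genes of the mitochondrial genome, ATP6 (-0.66 ± 0.175) fell adjusted over the list alone and 0 over all genes (median -0.33), and ND4, ND1 and ND6 had values of -0.49, -0.38 and -0.39. Of 32 epidermal genes, the basal keratin krt5 (-0.83 ± 0.182) and krt17 (-0.66 ± 0.162) fell adjusted over the list alone and 0 over all genes (median -0.26). The abundant krt4 had a value of -0.61 ± 0.224, and krt93, at under 1 CPM, one of 1.63 ± 0.515. The camera adjusted p was 8.56e-12 for ribosomal proteins, 0.000787 for the mitochondrial genome and 0.00198 for the epidermis. With an estimated correlation these calls were lost (adjusted p = 0.574, 0.75 and 0.568). The mitochondrial call was also lost without WT 67 (adjusted p = 0.128), the library that stood apart, and the epidermal call without hm41 69 (adjusted p = 0.0551), which stood apart on the other component. Removal of the 50 most abundant genes ended the epidermal call as well (camera adjusted p = 0.107).

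Of 17 microglia and macrophage genes, 3 fell adjusted over the list alone and 1, csf1ra, over all genes. Besides csf1ra these were lgals3bpb (-3.20 ± 0.818, SE), whose 5 counts in hm41 all came from hm41 70, so that hm41 had none without that library, and the chemokine gene ccl34b.1 (-1.67 ± 0.507), both under 0.5 CPM in WT. Of the whole list, 11 genes had lower and 6 higher values, and at an unadjusted p under 0.05 there were 3 lower and 0 higher by edgeR's test. Members without a call were hexb (0.40 ± 0.218) and, named after their values were seen, the macrophage gene mpeg1.1 (-0.55 ± 0.600, lower in every hm41 library than in any WT library) and the microglial gene apoeb (0.25 ± 0.201, with its sign turned to -0.04 without hm41 71). The list median was -0.20. With library totals alone, which moves the median of all genes by 0.22, it was 0.02, and relative to all genes -0.18. Camera gave an adjusted p of 0.0349, which became 0.596 with an estimated correlation. The list mean was -0.49 (SD 1.16), well below the median, and the list was not tested without csf1ra. The call was lost without WT 66, WT 68, hm41 69 or hm41 70 (adjusted p = 0.0806, 0.709, 0.0766 and 0.0825). It was also lost with no low-count filter (adjusted p = 0.0824).

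Another 7 lists were called higher by camera. In the glucocorticoid list, 1 of 25 genes, tat (0.85 ± 0.226, SE), a liver enzyme induced by cortisol, rose adjusted over the list alone and 0 over all genes. In that list hsd11b2, igfbp1a and g6pca.1 had values of 0.73, 0.73 and 0.64 (median 0.36, camera adjusted p = 0.00198). At an unadjusted p under 0.05, 6 of its genes were higher and 0 lower. With an estimated correlation its adjusted p was 0.75, and without hm41 71 it was 0.179. In the liver, gut and pancreas list, apoa2 (0.91 ± 0.193) and a2ml (0.67 ± 0.186) rose and apoa4b.2 (-0.60 ± 0.181) and the elastase-like zgc:112302 (-0.64 ± 0.164) fell adjusted over the list alone. Over all genes 0 of the 36 genes tested passed (median 0.45, camera adjusted p = 0.0077). At an unadjusted p under 0.05, 8 of its genes were higher and 2 lower. That call was lost with an estimated correlation (adjusted p = 0.794) and without WT 66 or hm41 71 (adjusted p = 0.0687 and 0.793). The other 5 lists had 0 members past the threshold of the edgeR test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 1 member of the cartilage and bone list, 6 of neurogenesis, 3 of muscle, 2 of oligodendrocytes and 3 of hypoxia, all higher. Their medians and camera adjusted p-values were 0.27 and 0.0072 for cartilage and bone (runx2b 1.24, lect1 0.52, col11a2 0.47, epyc 0.35), 0.20 and 0.00782 for neurogenesis (rtn1a 0.52, sox4b 0.51, hmgb2a 0.45, neurod4 0.46), and 0.12 and 0.0113 for muscle (mylz3 0.48, myom1a 0.47, pvalb1 0.49, casq1a 0.54). For oligodendrocytes and Schwann cells they were 0.29 and 0.0124 (mbpa 0.46, tspan2a 0.40, mpz 0.44, gpr17 0.67), and for hypoxia and glycolysis 0.18 and 0.0124 (egln3 0.78, pdk1 0.39, and ankrd37 with a mean of 0.131 CPM in WT and 0.310 CPM in hm41). With an estimated correlation the adjusted p was 0.794 for cartilage and bone and for muscle, 0.568 for neurogenesis and for oligodendrocytes, and 0.691 for hypoxia.

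Leaving out 1 library ended each of these 5 calls. Cartilage and bone was lost without WT 67, hm41 70 or hm41 71 (adjusted p = 0.171, 0.0953 and 0.286), muscle without WT 66, WT 67 or hm41 70 (0.0687, 0.978 and 0.0536), and neurogenesis without hm41 69 (0.0773), all by camera. Oligodendrocytes were lost without WT 66 or hm41 70 (0.0687 and 0.129), and hypoxia without WT 66, WT 67 or hm41 71 (0.0687, 0.0557 and 0.17).

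**Figure D3:**
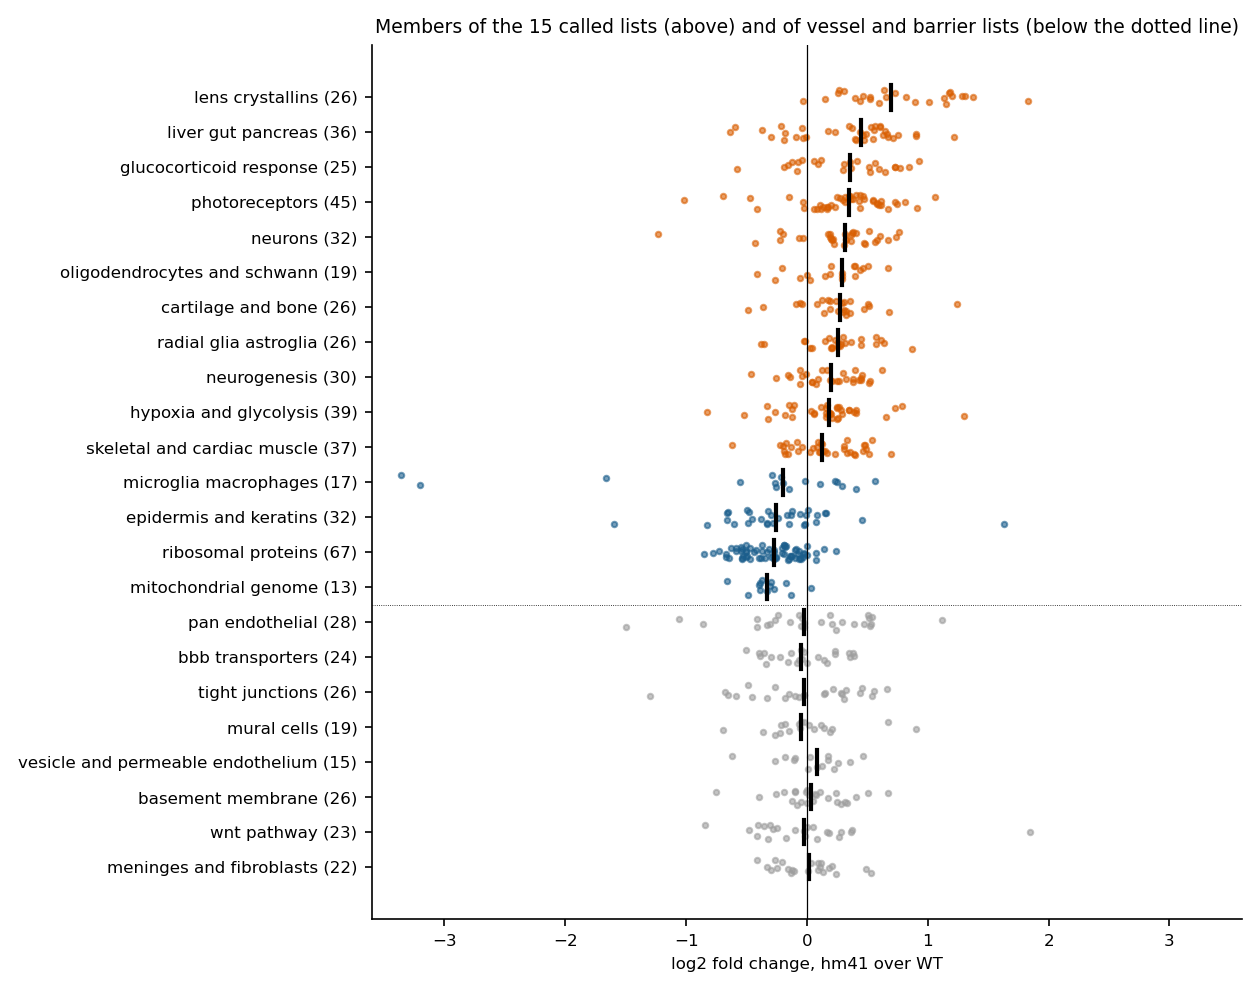
Each point is the log2 fold change (hm41 over WT) of 1 member gene, and each black bar the median of its list, with the number of tested members in brackets. The 15 lists called by camera stand above the dotted line (orange, higher in hm41; blue, lower), from lens crystallins with a median of 0.69 to the mitochondrial genome with -0.33, and 8 vessel, barrier and related lists stand below it in grey with medians between -0.05 and 0.08.

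Vessel and barrier lists showed no detectable shift against other genes in whole heads. None of the lists of endothelial genes (28 tested, median -0.03), barrier transporters (24, -0.05), tight junctions (26, -0.03), mural cells (19, -0.05), vesicle and permeable endothelium genes (15, 0.08), basement membrane (26, 0.03), Wnt pathway (23, -0.03) and meninges (22, 0.02) was called by camera, with adjusted p-values of 0.483 to 0.853. The mixed test of fry asks whether members change in either direction, without comparing them with other genes. It called the tight junction list (adjusted p = 0.00665) and the endothelial list (adjusted p = 0.0261). At an unadjusted p under 0.05 by edgeR's test, 1 of the 28 endothelial genes was higher and 2 were lower. That is about the share of all tested genes (10.4%). With library totals alone, which moves all genes up by 0.22, all 8 medians were above 0, and relative to all genes they lay between -0.07 and 0.07. Genes named here were chosen after their values were seen. The lipid transporter mfsd2aa had a log2 fold change of 0.39 ± 0.251 (SE), the endothelial claudins cldn5a and cldn5b 0.28 ± 0.266 and 0.46 ± 0.292, and the endothelial cadherin cdh5 0.53 ± 0.246. Of these, cdh5 had the smallest adjusted p (0.467, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the tight junction genes, 5 were lower at an unadjusted p under 0.05 and 0 were higher. They were cldn1 (-0.65 ± 0.240), cgnb (-0.68 ± 0.254), cldn11b (-0.45 ± 0.190), tjp2a (-0.49 ± 0.207) and tjp2b (-0.59 ± 0.259), none of which passed adjustment over the list alone. Of the 19 mural cell genes, the myosin light chain gene myl9b (0.67 ± 0.164) rose adjusted over the list alone, but not over all genes (adjusted p = 0.146 by edgeR's test). The glucose transporter gene slc2a1a had 0.35 ± 0.613 and the endothelial receptor gene kdrl 0.19 ± 0.226, and the signs of both turned when 1 library was left out (-0.06 for slc2a1a without WT 67, -0.05 for kdrl without hm41 69). The endothelial genes efnb2a and egfl7 had values of -1.06 ± 0.366 and -1.50 ± 0.561, the latter -2.63 without hm41 70.

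The other 17 lists were not called by camera (adjusted p 0.092 to 0.746). Medians above 0.1 were those of neural proteoglycans (0.18), cholesterol synthesis (0.13), immediate early genes (0.11), ionocytes and hair cells (0.21), neutrophils and inflammation (0.17), lipid transport (0.17) and aminergic and peptide neurons (0.15). Closer to 0 were the p53 response (0.02), erythrocytes (0.09), matrix proteases (0.08), oxidative phosphorylation (0.06), heat shock (0.07), the cell cycle (-0.06), interferon response (0.05), the circadian clock (-0.05) and pituitary and thyroid (-0.05). The median of pigment epithelium and melanocytes was -0.13. With library totals alone the negative medians turned to values above 0, while relative to all genes they stayed at -0.15 for pigment epithelium and melanocytes, -0.04 for the cell cycle, -0.03 for the circadian clock and -0.05 for pituitary and thyroid. Leaving out 1 library brought calls by camera, all higher in hm41: oxidative phosphorylation without WT 68 (adjusted p = 0.0183), cholesterol synthesis without hm41 69 or hm41 70 (0.00595 and 0.0131), and immediate early genes and neutrophils and inflammation without hm41 69 (0.0202 and 0.0184). Library totals alone brought cholesterol synthesis (higher, adjusted p = 0.0292), and a term for the LOC110438492 split brought pigment epithelium and melanocytes (lower, adjusted p = 0.00278). The mixed test of fry called neural proteoglycans (adjusted p = 0.0228), immediate early genes and the circadian clock (both 0.0129).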

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

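The removal of the 8 most abundant genes, the term for the LOC110438492 split and the lists without shared members were chosen after the data were seen, and the other alternatives before. The log2 fold change of spock1 stayed between -0.57 and -0.11 and that of mcamb between 0.00 and 0.41 under every alternative that gave one, and neither gene was called in any. Against 11 called genes (3 higher, 8 lower), relative log expression, upper quartile normalization and removal of the 8 most abundant genes called the same 11. Estimation without robustness and removal of the 50 most abundant genes each called 9 of them, without opn1sw1 and pcdh2g17. Library totals alone gave 47 (32 higher, 15 lower) and no low-count filter 131 (67 higher, 64 lower), both with all 11. A false discovery rate of 0.1 gave 24 (11 higher, 13 lower), a rate of 0.01 gave 7 (1 higher), and the test against a 1.2-fold change gave 8 (1 higher), by construction. Limma voom gave 18 (9 higher), 10 of them shared, and did not call aox5 (adjusted p = 0.064). DESeq2 gave 199 (139 higher, 60 lower) and shared 2. Its independent filtering left an adjusted p for 2463 genes and none for 9 of the 11, whose unadjusted p was 1.58e-06 or less. The filter of at least 2 CPM in at least 3 libraries left 8 of the 11 untested, and edgeR called 0 genes (0 higher, 0 lower) with 904 at an unadjusted p under 0.05. The term for the split gave 19 (7 higher), 10 of them shared. Without 1 library in turn the count was 6 to 44, with 0 to 21 higher and 6 to 23 lower. The lowest and highest counts came without hm41 70 (0 higher) and WT 68. Of the 15 called lists, 8 were called with the 2 CPM filter, 0 by camera with an estimated correlation (1 list at an unadjusted p under 0.05) and 0 by the directional test of fry (4 lists at an unadjusted p under 0.05). The mixed test of fry called 9 lists, 4 of them among the 15, and removal of the 50 most abundant genes left 13, without the epidermal and muscle lists. Without 1 library 10 to 15 lists were called, and without shared members 15. The odds ratio was 1.6 to 55.3 for chromosome 14 and 3.4 to 205.6 for the region around spock1, with no finite value without hm41 70. Of the named genes' values under alternatives, 1880 kept direction and side of the threshold, 62 passed it newly, 32 no longer passed it and 9 turned in sign, none of the 9 of a called gene. Genes without an adjusted p under an alternative were not counted there, among them 9 called genes with DESeq2 and 8 with the 2 CPM filter. With library totals alone csf1rb had 0.02, gstp1 0.12 and pax7a 0.24, and with the term for the split pax7a had 0.13. Without 1 library the range was -0.27 to 0.19 for pax7a, -0.064 to 0.688 for slc2a1a, -0.05 to 0.32 for kdrl and -0.042 to 0.425 for apoeb. Where no reason is given, the cause was not tested. Depth and spread limit what can be called: in data simulated with those of the real libraries, 4 of 50 genes changed 1.5-fold and 28 of 50 changed 2-fold were recovered.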

Other observations

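The pigment cell lists and the tests of the 3 patterns were chosen only after the results were seen, except the circular shifts and camera with an estimated correlation, which were planned as alternatives. The lists of proteoglycans, p53 response, ionocytes and hair cells were fixed before the data were examined. The list of neural proteoglycans and matricellular genes, the class spock1 belongs to, had 34 tested members and a median log2 fold change of 0.18 (camera adjusted p = 0.092). It was called by camera with no low-count filter (adjusted p = 0.0455) and by the mixed test of fry (adjusted p = 0.0228), but not by camera with an estimated correlation (adjusted p = 0.568). Besides spock2 and spock3, genes named after their values were seen were bcan, which encodes brevican (0.61 ± 0.192, SE), and sparcl1, a relative of SPARC (0.82 ± 0.270), each higher in every hm41 library than in any WT library but not past the threshold (adjusted p = 0.234 and 0.26 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the p53 response list foxo3b (0.57 ± 0.156) and sesn1 (0.54 ± 0.173) rose adjusted over the list alone, of 17 genes tested. Over all genes neither passed in edgeR's test (adjusted p = 0.193 and 0.252). In the list of ionocytes and hair cells the proton pump subunit atp6v1aa (0.62 ± 0.158) and tmc2a, a part of the hair cell transduction channel (2.28 ± 0.693, at 0.045 CPM in WT), rose adjusted over the list alone, of 22 tested. These too did not pass over all genes in edgeR's test (adjusted p = 0.165 and 0.227). None of these lists was called by camera at the settings of the report, and the genes were named after their values were seen.

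The gathering of called genes near spock1 was weighed against 3 technical explanations. Circular shifts of the calls along the gene order put as many on chromosome 14 in a share of 0.0191 of 10000 draws. The shifts keep the spacing of the calls, so this argues against chance only for the chromosome on which the calls gathered. It does not test their gathering or their nearness to spock1. Counting of csf1ra and gstp2 reads on the paralogs csf1rb and gstp1 (these and the protocadherins below were named after their values were seen) is argued against too: the highest hm41 library exceeded the lowest WT library by 0.59 CPM for both paralogs together, while csf1ra and gstp2 lost 3.98 CPM. A comparison by genotype also cannot separate the hm41 lesion from other differences linked to it. Sequence variants of the linked haplotype, which might keep reads from matching the reference, stay open. Of the 14 genes at an unadjusted p under 0.01 within 5 Mb, 64.3% were lower, and of the 7 clustered protocadherin genes among them 3 were lower and 4 higher (pcdh2g7 -2.49 ± 0.630, SE, with -1.85 without WT 66 and -3.36 without hm41 70; pcdh2g3 0.93 ± 0.220), so this cannot be told apart from a true change in these genes, including csf1ra.

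Some yellow pigment cell genes besides aox5 had lower values in hm41, a pattern found after aox5 was seen, with all genes here named after their values were seen. Of the 12 other tested xanthophore genes, 9 had lower values, 4 at an unadjusted p under 0.05, 3 fell adjusted over the list alone and 0 over all genes, among them the pteridine enzyme genes gch2 (-1.07 ± 0.294, SE) and pts (-1.33 ± 0.423, and -2.03 without hm41 70), while pax7a (-0.04 ± 0.259) and xdh (0.22 ± 0.201) did not follow (list median without aox5 -0.20, camera adjusted p = 0.0205 over 43 lists, adjusted p = 0.542 with an estimated correlation; with aox5 0.000735 and 0.542). The 5 genes lower at an unadjusted p under 0.05 (aox5, gch2, pts, slc2a11b and slc22a7a) lie on chromosomes other than 14. No tested gene of this list lies on chromosome 14, so that count was fixed by the list and tests nothing further. An effect of the linked region through csf1ra stays open. Less tissue of every pigment cell type, iridophores included, should lower iridophore genes too, but 7 of 9 were higher (pnp4a 0.94 ± 0.240). Their median was 0.22 (camera adjusted p = 0.0303, and 0.604 with an estimated correlation). The gap of xanthophore genes without aox5 to iridophore genes was lower in all 3 hm41 libraries than in any WT library. The difference was -0.69 (SD 0.172 in hm41 and 0.207 in WT). The exact permutation p was 0.1 over libraries, two-sided, the smallest that 6 allow, and 0.00235 over genes, which are not independent. These values lean against such a loss but cannot exclude it. The bound, no overlap and a gap wider than both SDs together, was chosen after 2 other forms of the test had been seen. A joint loss of xanthophores with melanophores stays open, since 10 of 11 melanophore genes were lower (median -0.18, camera adjusted p = 0.173). The fixed list of pigment epithelium and melanocytes had a camera adjusted p of 0.217, and 0.00278 with a term for the LOC110438492 split. Fewer xanthophores, a hypothesis that the lower csf1ra could go with since these cells need it, and lower pigment gene expression per cell cannot be told apart with 9 of 12 genes lower and no cell counts.

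The higher neural and eye lists and lower ribosomal and keratin lists were weighed last. The split of the libraries by LOC110438492 stays open as a cause. With a term for it 11 of the 15 lists were still called by camera. Cartilage and bone, liver, gut and pancreas, muscle, and hypoxia were not (adjusted p = 0.367, 0.418, 0.298 and 0.0984). The calls that remain cannot decide this, because camera at the preset correlation also called 5 to 19 lists in splits that mix the genotypes. A lower share of skin alone stays open: neuron genes had a mean log2 fold change of 0.24 (SD 0.39, 32 genes) and endothelial, mural and meningeal genes one of 0.00 (SD 0.41, 69 genes), but the gap between these sets per library was 0.19 higher in hm41 with overlap (SD 0.280 in hm41 and 0.120 in WT; exact permutation p = 0.4 over libraries, two-sided, and 0.00586 in a permutation test over genes, which are not independent). Whether members of a list that vary together between libraries account for the calls stays open. With the correlation estimated per list, 0 of the 15 lists were called by camera (1 list at an unadjusted p under 0.05). This loss cannot decide it, because lists with low estimates were lost too: radial glia (0.039) and neurogenesis (0.036), both at adjusted p = 0.568. For neural proteoglycans, with an estimate of -0.006 against the preset 0.01, the camera adjusted p went from 0.092 to 0.568. A difference between the genotypes in tissue proportions or stage remains untested.

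The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 11 genes and the highest of the others 9. For gene lists the real split gave 15 and the highest other 19, so that 2 of the 10 splits gave as many. Every split gave called lists, and the splits that mix the genotypes gave 5 to 19. With WT 66, WT 67 and hm41 70 against the rest there were 14, as with WT 66, WT 68 and hm41 71. The 15 list calls thus lie within what splits that mix the genotypes gave. The split with 19 lists sets WT 66, WT 67 and hm41 69 against the rest and follows LOC110438492. With a term for it the genotypes differed in 12 lists, 11 of the 15 and pigment epithelium and melanocytes, and in 19 genes. Within 5 Mb of spock1 the real split gave 4 called genes and the highest other 0, and for genes as for this region 1 of the 10 splits, the real one, gave as many.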
